A study of Mus musculus with 12 samples.

How the data were processed

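The series holds 12 expression arrays of total RNA, 6 of tumours from OS80 osteosarcoma cells with a Pth1r hairpin and 6 of tumours with a Renilla luciferase hairpin, and groups and tumour numbers were taken from the sample titles. Per the labels' protocols, tumours were homogenised in Trizol and the RNA was cleaned on columns before biotin labelling. The deposited values are log2 expression values, 1 per probe set and array; per the submitters' processing notes they were made with RMA, which corrects background, normalizes arrays to each other and summarises the probes of a probe set, and the notes name the genome build mm9. The version of RMA is not given in the sources used here. The 12 columns of the table were matched to samples by name, and the values were used as deposited. The arrays had median log2 values between 7.55 and 7.64 and a range from 2.63 to 14.63, and RMA tends to shrink differences of dim and of very bright probe sets. The labels give no scan date or batch, so array batches could not be examined. No arrays were identical: over the 30 pairs within groups the root mean square difference ran from 0.224 to 0.415 log2 units.

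Of 35556 probe sets, 23410 were listed in the platform annotation used here, 21789 with 1 gene symbol and 1621 with several, and 12146 were unlisted and stay unnamed. Symbols were looked up through Entrez identifiers in a table of RefSeq genes on assembly GRCm38.p6, which held 21698 of the identifiers and changed 0 symbols. That assembly differs from the authors' build, so no positions are given, and it served for names and for which genes neighbour each other. Where a gene had several probe sets the brightest over all 12 arrays was kept, which left 19938 genes.

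Knockdown minus control was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. Named genes were Pth1r, the 12 genes with the highest and the 12 with the lowest log2 fold change among those past the threshold with 1 sign in at least 5 of 6 pairs (leaving out predicted, olfactory and small RNA genes), and up to 4 members of each list with the smallest p. The rule also named Pthlh, which was not among the 19938 genes kept and was not analysed here. Other genes named in the text, Dmp1, Col1a1, Matn3, Tnfsf11, Fos, Mmp13, Apcdd1, Axin2, Ccn4, Mki67, Top2a, Car9, Pfkfb3, Vegfa, Asns, Dnajb9, Cd68, Col2a1, Pecam1, Cdh5, Kcnj8, Pdgfrb, Krt1 and Krt10, are list members chosen after their values were seen. No hairpin other than the 1 per group was measured. Effects of Pth1r, effects of the hairpin sequence and other differences between the cells that received each hairpin therefore cannot be told apart by this design. The p-values measure the spread among tumours and not among hairpins.

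The 23 gene lists covered bone and cartilage differentiation, cyclic AMP and Wnt targets, cell cycle, matrix proteases, hypoxia and glycolysis, p53 targets, the unfolded protein response, interferon, and markers of osteoclasts, macrophages, neutrophils, B and natural killer cells, endothelium, pericytes, fibroblasts, muscle, fat, keratinocytes, erythroid cells and Schwann cells. Each was tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, and p-values were adjusted over the lists. An exact permutation test of the mean of each list over tumours, with 924 splits, was added after the data were seen. So was the same test within pairs, over the 64 sign patterns of the pair differences, whose smallest two-sided p is 0.031. After adjustment over the 23 lists that p passes only if many lists reach it together, so failing there says little about a single list. Counts of genes adjusted over the list alone come from the same fit.

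The labels say which tumours grew on opposite flanks of 1 host, so the tumour numbers pair the samples. In the values, however, the deviations of paired tumours from their group means correlated at -0.38 to 0.24, above 0.1 in 2 of 6 pairs and below 0 in 3. The pair was left out of the main model and used as a block in an alternative. Other alternatives were the pair as a random effect, a filter on genes below the median probe set, quantile normalization, median centring, a trended and robust variance, array weights, the mean of a gene's probe sets, all probe sets, an unmoderated test, other thresholds, each tumour or pair left out in turn, and, added after the data were seen, leaving out the 3 tumours with high keratinocyte genes.

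The fit was tested on simulated data of 19938 genes with 6 against 6 arrays and known changes. It recovered 54.4% of 68 genes changed by 0.3 on the log2 scale, 92.4% of 66 changed by 0.6 and 100% of 66 changed by 1, with 5 false calls. Noise was drawn independently for each gene, and far fewer genes were changed than were called in the tumours. These rates therefore need not hold for the real data, where genes move together. For runs of neighbouring genes, 9956 genes brighter than the median gene were put in order along the assembly, medians were taken over windows of 25 genes, and windows beyond the most extreme of 1000 shuffled orders were joined into runs. Plots were drawn with matplotlib 3.10.9.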

Results

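Total RNA of 12 mouse tumours was measured on expression arrays. All were grown from OS80, a luciferase-tagged osteosarcoma cell line that came from a tumour of an Osx-Cre mouse with floxed p53 and Rb alleles, where the recombinase is active in the osteoblast lineage. The cells of 6 tumours carried a short hairpin RNA against Pth1r, and those of 6 control tumours carried a hairpin against Renilla luciferase, a gene that mice lack. The tumours grew for 4 weeks under the skin of the flank of nude mice, with 1 tumour of each group on opposite flanks of the same host, so that the tumours form 6 pairs. Each array held 35556 probe sets, with median log2 signals between 7.55 and 7.64, and the number of arrays limits the precision of every value.

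The first comparison asked how far the hairpin lowered its target. Pth1r, the receptor for parathyroid hormone and parathyroid hormone-related protein, fell in the knockdown tumours to a mean log2 signal of 10.97 ± 0.12 (SD, n = 6) against 11.66 ± 0.11 in the controls (probe set 10597239, Entrez gene 19228). The log2 fold change was -0.69 (SE 0.066, limma with Benjamini-Hochberg adjustment, adjusted p = 4.2e-06), which left 61.9% of the control signal (95% confidence interval 56.2 to 68.3). Pth1r was lower in the knockdown tumour of 6 of 6 pairs, and the ranges of 10.82 to 11.14 and 11.54 to 11.82 did not overlap. An exact two-sided permutation test of the 12 values gave p = 0.0022, the smallest value that its 924 splits allow, and an exact test within pairs gave p = 0.031, the smallest that 64 sign patterns allow. The 24 genes that neighbour Pth1r had a median log2 fold change of -0.033.

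The second comparison asked which genes differed between knockdown and control tumours. The largest rises among named genes were those of the cyclin gene Ccnb3 (log2 fold change 3.24, SE 0.12), the potassium channel gene Kcnk1 (2.77, SE 0.19), Bmp3 (2.76, SE 0.15), which encodes an antagonist of bone morphogenetic protein signalling, and the nicotinic receptor subunit gene Chrna4 (2.68, SE 0.18). Bmp3 went from a log2 signal of 7.51 ± 0.32 in control tumours to 10.27 ± 0.29 in knockdown tumours (SD, n = 6 each), a 6.79-fold difference. Chrdl1, another bone morphogenetic protein antagonist, rose by 2.55 (SE 0.21), Cthrc1 by 2.52 (SE 0.14), Adamts18 by 2.43 (SE 0.18) and Nell1, which encodes a secreted osteogenic protein, by 2.37 (SE 0.14). Lgi1, Cdo1, Grin2c and Ranbp3l rose by 2.19 to 2.31. Ccnb3 and Lgi1 were dim in control tumours, at log2 signals of 5.01 and 6.21, where lower quartiles of the arrays were 5.97 to 6.06, so the sizes of their changes are uncertain. These 12 genes were higher in the knockdown tumour of 6 of 6 pairs, and their limma adjusted p-values lay between 2.6e-09 and 5.0e-05.

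The deepest falls were those of Hapln1 (log2 fold change -2.43, SE 0.14), whose product links hyaluronan to aggrecan in cartilage, the ephrin receptor gene Epha3 (-2.31, SE 0.13), the cation channel gene Trpa1 (-2.21, SE 0.18) and the transcription factor gene Zfhx4 (-2.18, SE 0.082). Zfhx4 went from 11.53 ± 0.16 in control tumours to 9.35 ± 0.15 in knockdown tumours (SD, n = 6 each). Nkd2, whose product restrains Wnt signalling, fell by 2.11 (SE 0.11), and the amino acid transporter gene Slc6a15 fell by 2.05 (SE 0.18). Nsg1, Lipi, Mpped2, Chrna1, Jph1 and Map2 had log2 fold changes between -1.94 and -1.72. Hapln1 and Mpped2 were dim in knockdown tumours, at log2 signals of 6.11 and 5.87, so the sizes of their falls are uncertain. All 12 were lower in the knockdown tumour of 6 of 6 pairs, with limma adjusted p-values between 2.6e-09 and 6.7e-05. Nkd2 lies in a run of neighbouring genes, Ptdss1 to Pdcd6, whose 23 members had a median log2 fold change of -0.43.

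**Figure D1:**
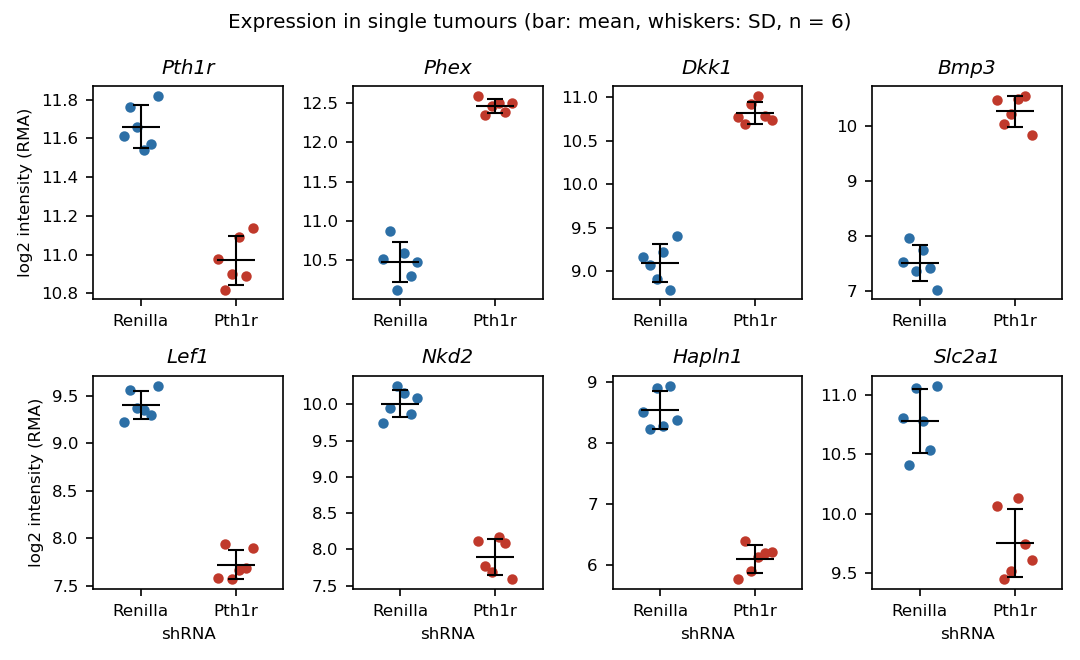
Log2 array signal (vertical axis, RMA values) of 8 genes in single tumours with the Renilla or the Pth1r hairpin. Each point is a tumour, the bar the group mean and the whiskers the SD over n = 6; Pth1r, Lef1, Nkd2, Hapln1 and Slc2a1 were lower and Phex, Dkk1 and Bmp3 higher in knockdown tumours, and the ranges of the groups did not overlap for any of the 8.

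Of 19938 genes, 5691 (28.5%) changed at an adjusted p under 0.05 in limma, 2247 of them higher and 3444 lower in knockdown tumours. Among the 9956 genes brighter than the median gene and placed in order along the assembly, 44.7% changed. Of the ordered genes 2912 were called lower and 1535 higher in knockdown tumours, and their median log2 fold change was -0.052. Counts and directions of called members in lists of bright genes are to be read beside these values. Most changes were small: the median absolute log2 fold change of the called genes was 0.31, and 195 genes changed at least 2-fold, 88 higher and 107 lower. The pair difference had 1 sign in all 6 pairs for 4718 of the called genes. The share of higher genes among the calls was 39.5%, and it was 28.8% (1735 higher, 4285 lower) once each array was centred on its median.

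Among genes of bone, those of late osteoblasts and osteocytes included some of the strongest changes. Phex, an osteocyte endopeptidase gene whose loss causes phosphate wasting, rose by 1.98 (SE 0.099) and Dkk1, which encodes a secreted Wnt inhibitor, rose by 1.73 (SE 0.094). Dmp1, a matrix gene of osteocytes, rose by 0.65 (SE 0.17), while the osteomodulin gene Omd fell by 1.38 (SE 0.22). Of 19 measured members of the mature osteoblast and osteocyte list, 6 rose, 2 fell and 11 did not pass, and adjusted over the list alone 7 rose and 2 fell. The list's median log2 fold change was 0.10, and 0.065 once each array was centred on its median, and it ranked above other genes in camera (adjusted p = 0.013, higher in 6 of 6 pairs by the list mean; adjusted p = 0.52 with an estimated correlation). The early osteoblast list split: 5 of 17 members rose and 4 fell (5 and 5 adjusted over the list alone), with a median of 0.049 and a camera adjusted p of 0.49. Cdh11 rose by 0.24 (SE 0.039) and Col5a2 by 0.49 (SE 0.052), and Alpl, the bone alkaline phosphatase gene, fell by 0.26 (SE 0.053). Col1a1 stood at 13.98 in knockdown and 13.94 in control tumours, with an adjusted p of 0.43 in limma. Col5a2 lies in a run of neighbouring genes, Rab23 to Gm10561, with a median of 0.27.

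More cartilage genes rose than fell. The lubricin gene Prg4 rose by 1.87 (SE 0.23), Col11a2 by 0.88 (SE 0.090) and Sox9, the main transcription factor of chondrocytes, by 0.48 (SE 0.085). Of 22 measured chondrocyte genes 10 rose and 2, Hapln1 and Matn3, fell, the same counts as when adjusted over the list alone. The median was 0.19 (camera adjusted p = 0.0060, higher in 5 of 6 pairs; adjusted p = 0.52 with an estimated correlation). Col2a1, the major cartilage collagen gene, had a log2 fold change of 0.21 (SE 0.088) with an adjusted p of 0.093 in limma.

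The receptor signals in part through cyclic AMP, and the targets of that pathway moved in both directions. Nr4a2, an immediate early gene, fell by 0.86 (SE 0.083), Lif by 0.46 (SE 0.069), Nr4a1 by 0.41 (SE 0.070) and Tnfsf11, which encodes the osteoclast differentiation factor RANKL, by 0.53 (SE 0.094). Fos fell by 0.27 (SE 0.066). Hcar1, a lactate receptor gene, rose by 1.04 (SE 0.088), and the collagenase gene Mmp13 rose by 0.24 (SE 0.042). Of 28 members of the cAMP-CREB and immediate early list 6 rose and 8 fell, with the same counts adjusted over the list alone, a median of -0.12 and a camera adjusted p of 0.62. Pthlh, the gene of parathyroid hormone-related protein, was not among the 19938 genes kept and was not analysed here.

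Several Wnt target genes fell steeply. Lef1, a transcription factor gene of the pathway, fell by 1.68 (SE 0.082), Apcdd1 by 1.11 (SE 0.22), Axin2, a general reporter of the pathway, by 0.55 (SE 0.080), and Myc by 0.38 (SE 0.055). In contrast Rnf43 rose by 0.63 (SE 0.085) and Ccn4 by 0.36 (SE 0.063). Of 18 Wnt targets 3 rose and 6 fell, the same adjusted over the list alone. The median was -0.017 and the mean -0.24, and camera gave an adjusted p of 0.40, whereas an exact permutation test of the list mean over tumours gave an adjusted p of 0.022, and 0.072 within pairs, with the mean lower in 6 of 6 pairs. Lef1 lies in a run of neighbouring genes, Fnbp1l to Adh7, with a median of -0.36 over 42 genes. Nkd2, also a member of the list, had a log2 fold change of -2.11 and lies in the run Ptdss1 to Pdcd6. Nkd2 and Lef1 had the lowest log2 fold changes of the list and pull its mean down. Most of the fall of the mean came from them, and both lie in lower runs. The mean was not tested without them.

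Genes of cell division were lower in knockdown tumours. Cdc20, an activator of the anaphase-promoting complex, fell by 0.63 (SE 0.078), Cdca8 by 0.56 (SE 0.075), Aurkb by 0.53 (SE 0.081) and the replication licensing gene Mcm3 by 0.41 (SE 0.059). Of 32 cell cycle genes 14 fell in limma, or 17 adjusted over the list alone, and none rose, by unadjusted p either. The median was -0.17 (camera adjusted p = 0.00019, lower in 6 of 6 pairs; adjusted p = 0.67 with an estimated correlation). Mki67 and Top2a had log2 fold changes of -0.19 (SE 0.069) and -0.012 (SE 0.089), with limma adjusted p-values of 0.059 and 0.94.

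Genes of glycolysis and the response to low oxygen also fell. The phosphofructokinase genes Pfkl and Pfkp fell by 1.05 (SE 0.12) and 0.80 (SE 0.11), the glucose transporter gene Slc2a1 by 1.03 (SE 0.14) and Car9, a carbonic anhydrase gene induced by low oxygen, by 0.60 (SE 0.15). Of 22 members 12 fell and 1, Pfkfb3, rose, the same adjusted over the list alone, and the median was -0.30. Camera gave an adjusted p of 0.0018, lower in 6 of 6 pairs, with an adjusted p of 0.67 with an estimated correlation and of 0.076 when only genes brighter than the median probe set were kept. Vegfa had a log2 fold change of -0.35 (SE 0.15) and an adjusted p of 0.097 in limma.

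More genes of the unfolded protein response fell than rose. Sel1l fell by 0.43 (SE 0.049), Creld2 by 0.46 (SE 0.063), Asns, the asparagine synthetase gene, by 0.57 (SE 0.11) and Atf4 by 0.29 (SE 0.043), while Dnajb9 rose by 0.31 (SE 0.075). Of 20 members 8 fell and 4 rose, the same adjusted over the list alone, with a median of -0.079. All 20 were brighter than the median probe set in control tumours, and bright genes leaned the same way. Of the bright genes put in order along the assembly, 2912 were called lower and 1535 higher. The counts of called members therefore do not set this list apart from bright genes. The camera adjusted p of 0.066 missed the threshold, and it was 0.043, 0.047 and 0.037 without knockdown tumour 1, knockdown tumour 5 and control tumour 2. Without the 3 tumours with high keratinocyte genes the median was -0.12 and the camera adjusted p 0.034, and without pair 1 or pair 2 the camera adjusted p was 0.033 and 0.036. In each of these refits it was at least adjusted p = 0.54 with an estimated correlation. Sel1l lies in the run Ptgr2 to Ubr7, with a median of -0.36 over 63 genes. Atf4 lies in no run, but its 24 neighbours had a median of -0.34, so its fall did not exceed theirs. The 24 neighbours of Creld2 had a median of -0.28. Of 18 p53 targets 4 rose and 2 fell (5 and 3 adjusted over the list alone), with a median of 0.11 and a camera adjusted p of 0.14. Among them Ddit4l rose by 0.68 (SE 0.10), Sesn1 by 0.45 (SE 0.056) and Trp53inp1 by 0.42 (SE 0.062), and the DNA polymerase gene Polk fell by 0.71 (SE 0.069).

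Proteases of the matrix and their inhibitors went both ways. Plat, the tissue plasminogen activator gene, fell by 1.18 (SE 0.14) and Adamts4, an aggrecanase gene, by 0.63 (SE 0.083), while Mmp16 rose by 0.38 (SE 0.054) and Mmp10 by 0.35 (SE 0.054). Of 22 members 6 rose and 7 fell, the same adjusted over the list alone, with a median of -0.015 and a camera adjusted p of 0.78.

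Macrophage genes were higher in knockdown tumours. Adgre1, which encodes the macrophage antigen F4/80, rose by 0.96 (SE 0.12), the complement genes C1qc and C1qb by 0.93 (SE 0.14) and 0.68 (SE 0.11), and the mannose receptor gene Mrc1 by 0.82 (SE 0.12). Of 23 members 15 rose and none fell, or 16 and 0 adjusted over the list alone, and the median was 0.48. Camera gave an adjusted p of 3.8e-07, higher in 6 of 6 pairs, with an adjusted p of 0.52 with an estimated correlation. Cd68, a marker that osteoclasts share, had a log2 fold change of 0.0030 (SE 0.057, limma adjusted p = 0.98). Osteoclast genes did not follow: 6 of 17 fell, among them Car2 by 0.91 (SE 0.13), the fusion gene Ocstamp by 0.58 (SE 0.095) and Nfatc1 by 0.21 (SE 0.053), and 1, Itgb3, rose by 0.36 (SE 0.083). Adjusted over the list alone 8 fell and 1 rose, the median was -0.11, and the camera adjusted p was 0.066. That adjusted p was 0.018, 0.033 and 0.023 without knockdown tumour 6, control tumour 3 and control tumour 6, 0.031 and 0.0058 without pair 3 and pair 6, and 0.027 with array weights, but at least adjusted p = 0.61 with an estimated correlation in each of these refits. Interferon-induced genes were also higher: 9 of 25 rose and 1, Xaf1, fell, the same adjusted over the list alone. Rsad2 rose by 0.99 (SE 0.18), Ddx60 by 0.72 (SE 0.17) and Mx2 by 0.51 (SE 0.12), and the median was 0.27 (camera adjusted p = 0.0017, higher in 6 of 6 pairs; adjusted p = 0.71 with an estimated correlation). An exact permutation test of the interferon list mean over tumours gave an adjusted p of 0.089, and 0.072 within pairs.

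Endothelial genes were higher as well. The angiopoietin receptor gene Tek rose by 0.74 (SE 0.091), Adgrl4 by 0.54 (SE 0.059), Emcn by 0.47 (SE 0.080) and Ptprb by 0.47 (SE 0.068). Of 25 members 12 rose and none fell, or 15 and 0 adjusted over the list alone. The median was 0.23 (camera adjusted p = 8.3e-07, higher in 6 of 6 pairs; adjusted p = 0.52 with an estimated correlation). Pecam1 and Cdh5 had log2 fold changes of 0.15 (SE 0.087) and 0.14 (SE 0.077), with adjusted p-values of 0.24 and 0.19. Pericyte and smooth muscle genes went both ways, since 4 of 18 rose and 6 fell, the same adjusted over the list alone. Their median was 0.0090 and the camera adjusted p 0.87. The pericyte genes Rgs5 and Cspg4 rose by 1.18 (SE 0.098) and 0.73 (SE 0.11). The pericyte genes Kcnj8 and Pdgfrb had log2 fold changes of -0.67 (SE 0.13) and -0.33 (SE 0.073). The smooth muscle actin gene Acta2 fell by 0.69 (SE 0.12), while the smooth muscle myosin gene Myh11 rose by 0.41 (SE 0.068). Neither cell type thus moved in 1 direction. Emcn lies in the run Fnbp1l to Adh7, whose median was -0.36.

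**Figure D2:**
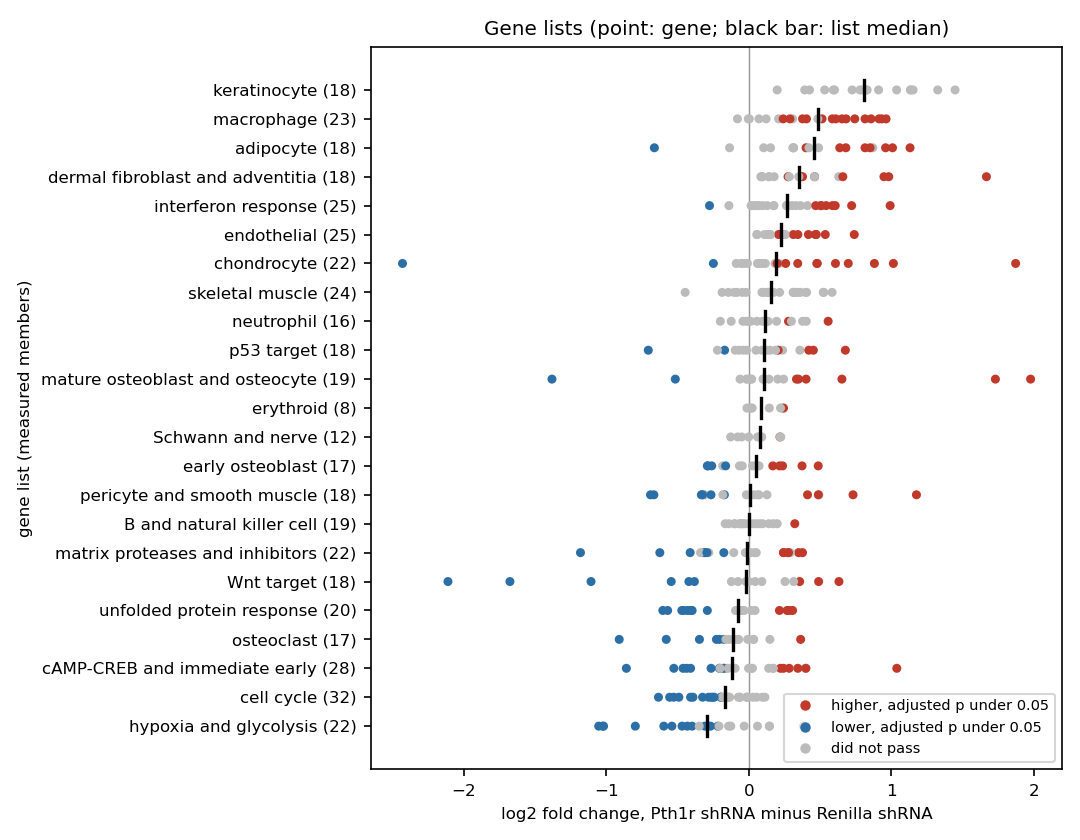
Log2 fold change, Pth1r hairpin minus Renilla hairpin (horizontal axis), of the measured members of 23 gene lists. Each point is a gene, coloured where its limma adjusted p was under 0.05, and the black bar is the list median, which ran from -0.30 for hypoxia and glycolysis to 0.81 for keratinocyte genes, none of which passed.

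Genes of dermal fibroblasts and fat stood higher in knockdown tumours. Sfrp2, which encodes a secreted modulator of Wnt signalling, rose by 1.67 (SE 0.13), Fmo2 by 0.95 (SE 0.10), Lum by 0.98 (SE 0.26) and Cd34 by 0.36 (SE 0.092). The call of Lum, with a limma adjusted p of 0.012, ended without pair 5 (0.056) and without moderation of the variances (0.051). Of 18 fibroblast and adventitia genes 8 rose and none fell, the same adjusted over the list alone, with a median of 0.35 (camera adjusted p = 0.00019, higher in 6 of 6 pairs; adjusted p = 0.62 with an estimated correlation). Of 18 adipocyte genes 8 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median of 0.46 (camera adjusted p = 0.0013, higher in 5 of 6 pairs; adjusted p = 0.67 with an estimated correlation). An exact permutation test of the adipocyte list mean over tumours gave an adjusted p of 0.066, and 0.11 within pairs. The fatty acid carriers Cd36 and Fabp4 rose by 1.13 (SE 0.16) and 0.81 (SE 0.13), and Car3, which the osteocyte list also holds, by 0.40 (SE 0.072), while the acyltransferase gene Agpat2 fell by 0.66 (SE 0.092).

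Keratinocyte genes were high in 3 tumours, knockdown tumours 1 and 4 and control tumour 2. There the median of 18 genes was 3.25 log2 units above the other 9 tumours, with 5.57 for the epidermal keratin gene Krt1. Between the groups none of the 18 passed in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The median log2 fold change was 0.81 and the camera adjusted p was 0.066 (0.049 with the pair as a block, and 0.0086 at a median of 0.77 once each array was centred on its median). That p was 0.032, 0.016, 0.017 and 0.00043 without knockdown tumours 2, 3 and 6 and control tumour 2, where the medians were 1.00, 1.09, 1.11 and 1.43. The camera adjusted p was 0.034 without pair 3 and 0.044 without pair 6. Without pair 2 the median was 1.65 (camera adjusted p = 0.00012), without knockdown tumours 1 and 4 it was 0.52 and 0.26, and without pairs 1 and 4 it was 0.37 and 0.16. In each of these refits the list had at least adjusted p = 0.54 with an estimated correlation. An exact permutation test of the list mean over tumours gave p = 0.24. Trp63, a transcription factor gene of basal keratinocytes, passed without control tumour 2 (adjusted p = 0.0069 in limma) and without knockdown tumour 6 (0.032), and Krt14 without control tumour 2 (0.028). Trp63 also passed in limma on bright genes alone (adjusted p = 0.035), with array weights (0.0498) and without pair 2 (0.0066). Krt14 also passed without pair 2 (limma adjusted p = 0.022). Without the 3 tumours both passed (limma adjusted p = 0.00051 and 6.1e-05). Without the 3 tumours, an alternative chosen after the data were seen, 5124 genes changed, 2036 higher and 3088 lower, and 4664 of them were among the 5691. The macrophage and endothelial medians were then 0.47 and 0.18, the fibroblast and adipocyte medians 0.25 and 0.38, and the interferon median 0.19.

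**Figure D3:**
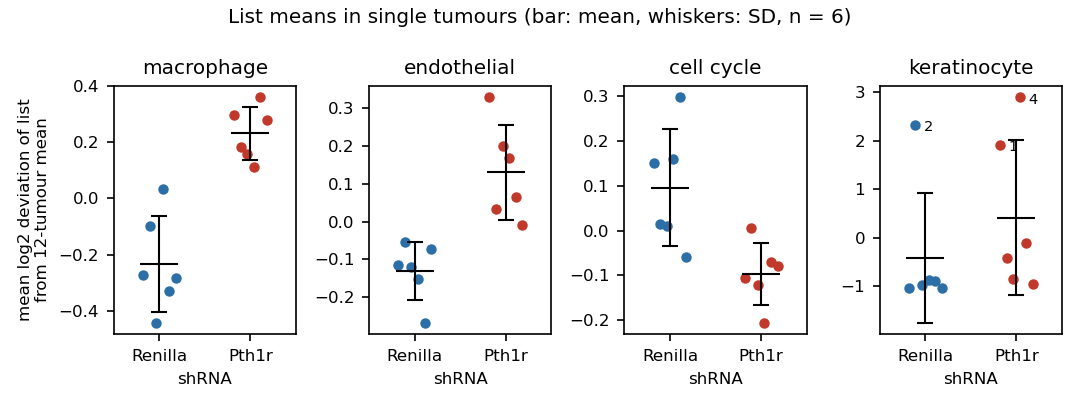
Mean log2 deviation of 4 gene lists from the mean of all 12 tumours (vertical axis) in single tumours with the Renilla or the Pth1r hairpin. Each point is a tumour, the bar the group mean and the whiskers the SD over n = 6; the macrophage means were 0.23 ± 0.095 in knockdown and -0.23 ± 0.17 in control tumours, and numbers mark the tumours with high keratinocyte genes.

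In other cell types few genes passed. Of 16 neutrophil genes the receptor gene Csf3r rose by 0.56 (SE 0.092) and Mmp8 by 0.28 (SE 0.095), higher in 4 of 6 pairs, whose limma adjusted p was 0.041, and 0.080 with the pair as a block. Without knockdown tumours 1, 3 or 6 or control tumours 3, 5 or 6, each left out alone, the adjusted p of Mmp8 in limma was 0.080, 0.083, 0.061, 0.086, 0.093 and 0.076. Adjusted over the list alone 1 of the 16 rose, and the median was 0.11 (camera adjusted p = 0.17, and 0.049 without pair 2, where it was adjusted p = 0.54 with an estimated correlation). Of 19 B and natural killer cell genes Cd79b rose by 0.32 (SE 0.094, adjusted p = 0.019, and 0.065 with the pair as a block), and adjusted over the list alone none did, while by unadjusted p in limma 2 were higher and 1 lower. None of the neutrophil or the B and natural killer cell genes was brighter than the median probe set in control tumours. The median of that list was -0.0016, its mean 0.018 and the direction in camera upward, with an adjusted p of 0.67. Of 8 erythroid genes Klf1 rose by 0.24 (SE 0.066, adjusted p = 0.013, and 0.052 with the pair as a block), with 1 adjusted over the list alone, a median of 0.083 and a camera adjusted p of 0.22. Of 12 Schwann cell and nerve genes Egfl8 rose by 0.22 (SE 0.056), with 1 adjusted over the list alone, a median of 0.076 and a camera adjusted p of 0.49. None of 24 skeletal muscle genes passed in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Their median was 0.15 with a camera adjusted p of 0.49. Without control tumour 3 the median was 0.63 with a camera adjusted p of 0.00094 (adjusted p = 0.64 with an estimated correlation), and the nebulin gene Neb passed (limma adjusted p = 0.034). In that tumour the muscle enolase gene Eno3 was at 11.66 against 10.47 to 10.75 in the other control tumours.

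Of the 23 lists 9 passed camera with a preset correlation of 0.01, 7 higher and 2 lower, and none passed with an estimated correlation, where no list had an unadjusted p under 0.05 either. With an estimated correlation none passed in 22 refits either, without single tumours, without pairs, without the 3 tumours with high keratinocyte genes, with median centring, with the pair as a block and with array weights (lowest adjusted p = 0.44), and 5 of 506 list tests had an unadjusted p under 0.05. In 31 of 100 splits of the 12 tumours at least 9 lists passed camera, so the number of lists does not set the groups apart from other splits, and the counts of single genes carry the comparison. An exact permutation test of each list's mean over tumours, chosen after this was seen, put 11 lists past the threshold after Benjamini-Hochberg adjustment. These held the 9 apart from the interferon and adipocyte lists, and in addition the Wnt target, p53 target, unfolded protein response and osteoclast lists, with adjusted p-values of 0.022, 0.012, 0.014 and 0.0498. That test leaves the pairs out: an exact permutation test within pairs put none of the 23 lists past the threshold (lowest adjusted p = 0.072), while 10 had an unadjusted p of 0.031, the smallest it allows. After adjustment over 23 lists that p passes only if more lists than these reach it. The outcome therefore says little about single lists.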

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

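The shuffles of gene order, the tests of skin and of the knockdown as sources of the keratinocyte genes, the comparison of macrophage with osteoclast genes, the separate tests of skin for fibroblasts and fat, the count of list members in runs and the refits without 3 tumours were chosen after the results were seen.

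In 22 of 272 groups of 6 tumours (113 named genes and 23 list means, each in both groups) a single tumour stood apart from the other 5, with a gap to its nearest neighbour, as a share of the group's range, above the 95% critical value of Dixon's test. Chance flags about 1 in 20 such groups. Many were in control tumour 2: its keratinocyte list mean (0.953 of the range), Trp63 (0.925), Krt14 (0.898), Krt17 (0.898) and Perp (0.792) were high, as were Fabp4 (0.743) and the means of the neutrophil (0.722), adipocyte (0.697) and B and natural killer cell (0.684) lists. In control tumour 3, Ddit4l (0.807) and Eno3 (0.765) were high and Tek (0.769) was low, and in control tumour 6 Adgrl4 (0.630) was high. In knockdown tumour 6, Kcnk1 (0.747), Cthrc1 (0.659) and Alpl (0.641) were low, and in knockdown tumour 5 Sox9 (0.671) and Mmp16 (0.644) were high and Egfl8 (0.665) was low. In knockdown tumour 3 Slc6a15 (0.700) was low, and in knockdown tumour 4 Nr4a2 (0.675) was low and the neutrophil mean (0.641) high.

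Other splits of the 12 tumours into 6 and 6 were fitted to see how often they call as much as the real one. Of 100 splits, 1, the real one, called as many as 5691 genes, and the highest other called 3; for genes higher (2247) it was again 1 with 3 as the highest other, and for genes lower (3444) 1 with 0. A chance division of the tumours is thus argued against for these counts. However, the other splits mix both groups in each arm, which adds the group difference to their spread. The splits cannot tell an effect of the hairpin from other differences between the cells that received each hairpin. Among the 32 splits that part all 6 pairs, as the real one does, 1 called as many genes and the highest other called 3, and the remaining splits keep some pairs together. For the 9 lists past camera, 31 of 100 splits gave as many and the highest other gave 17, and 15 of the 32 gave as many with 14 as the highest other, so chance cannot be excluded for the number of lists.

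Genes next to each other moved together in 13 runs, 9 lower and 4 higher in knockdown tumours, the strongest being 32 genes from Htr2a to Olfm4 with a median log2 fold change of -0.65 (quartiles -1.23 and -0.28, and -0.77 to -0.52 over the 6 pairs). A random order is argued against by the largest window shift of 0.799, where the highest of 1000 shuffles reached 0.2996, and skin in 3 tumours by a median of -0.66 without them. In a search on every other gene, the 7 genes left out between Enox1 and Olfm4 had a median of -1.24 and all 7 were lower, so a candidate explanation is a different copy number of such intervals in the cells that received each hairpin. The runs hold 421 of the 4447 called genes among those ordered. Of the 9 lists past camera 6 had 0 members in runs and 3 had 1, at most 4.35% of a list. The runs hold 5.46% of all ordered genes, and dim members could not lie in a run. These low shares therefore do not set the lists apart from other genes. Other lists were not counted. Runs were kept only beyond the most extreme of 1000 shuffles, so weaker shared shifts are left out. Over all ordered genes neighbours correlated with a Spearman's rho of 0.329, so how much of the calls goes with position cannot be told. Copy number was not measured, and a shared response of neighbouring genes to the knockdown stays open as well.

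The 18 keratinocyte genes stood high in knockdown tumours 1 and 4 and control tumour 2. Control tumour 2 had a mean deviation of 2.33 and the highest of the other 4 knockdown tumours -0.11, which the knockdown as the whole source would not give, although this restates where the genes were high and an effect of it on their level stays open. The genes rose in step, with a median pairwise correlation of 0.959 over the 12 tumours and the same 3 tumours on top for 18 of 18 genes, which is consistent with skin taken along at dissection. In the other 9 tumours 2 of the 18 genes were above the median probe set, and in the 3 tumours Krt1 reached 11.66 and Krt10 11.43. Skin in amounts too small to stand out stays open for the other tumours: without the 3, the list's median was 0.32 in favour of knockdown tumours (adjusted p = 0.00064 in camera, adjusted p = 0.57 with an estimated correlation, 4 of 18 genes past the threshold in limma).

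Genes of macrophages and endothelium, and of fibroblasts and fat, stood higher in knockdown tumours by camera with a preset correlation. None of these lists passed camera with an estimated correlation (adjusted p at least 0.52). None passed the exact permutation test within pairs (adjusted p at least 0.072), where the smallest p passes only if many lists reach it together. Skin in the 3 tumours is argued against for macrophages and endothelium, whose medians kept at least 77.1% without them. By its median, which kept 83.8%, it is argued against as the whole source for fat. However, the adipocyte list mean was highest of its group in knockdown tumours 1 and 4 (0.64 and 0.76) and control tumour 2 (0.18), so a part played by skin stays open. For fibroblasts skin cannot be told apart: the median kept 69.5%, between the bounds set for either outcome. Their list mean was lowest in control tumour 2 (-0.56). The bounds were set for list medians only. A lower share of tumour cells alone would raise the markers of every host cell type alike. The macrophage list mean moved 0.61 log2 units further than the osteoclast mean, which was lower (exact permutation p = 0.0022, and 0.031 within pairs, the smallest that each gives). That argues against a lower share as the only change. Osteoclasts may also have changed on their own, and Tnfsf11, the gene of their differentiation factor, had a log2 fold change of -0.53. A lower share thus stays open for the macrophage and endothelial genes. In control tumours 20 of 23 macrophage, 22 of 25 endothelial and 17 of 17 osteoclast genes were brighter than the median probe set, and whether tumour cells express them was not measured. A change in macrophages and vessels with the knockdown remains a hypothesis, and expression of such genes by the tumour cells stays open.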

How the results depend on the processing

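The exact tests of list means, over tumours and within pairs, the refits with an estimated correlation and the refit without the 3 tumours with high keratinocyte genes were chosen after the data were seen. The Pth1r log2 fold change stayed past the threshold in all 29 alternatives, from -0.74 to -0.64. The 5691 changed genes became 4988 to 5689 without single tumours, 4601 to 5545 without pairs, 5172 with the replicate block (2007 higher, 3165 lower, 4982 shared), which ended the calls of Mmp8, Cd79b and Klf1 and put Tfrc and the keratinocyte list past the threshold but changed no other call of a named gene or list, and 195 when a 2-fold change was also required (88 higher, 107 lower), by construction of a stricter rule. The calls of Mmp8, Cd79b, Klf1 and Lum were the ones lost among named genes, in 26 results over all alternatives. Over all probe sets 3371 were higher, where more features were tested. Of the 23 lists 9 passed camera, and 0 passed it with an estimated correlation, which lowers the effective number of genes. Fry passed 10 and exact tests over tumours passed 11. Exact tests within pairs passed 0, but their smallest p of 0.031 passes after adjustment only if many lists reach it together. With an estimated correlation 0 passed in each of 22 refits. Lists that did not pass changed direction: with the pair as a block the pericyte list turned to the downward direction in camera at a median of 0.0090, with median centring the protease list turned upward at a median of -0.054, and without the 3 tumours the pericyte and skeletal muscle medians were -0.066 and -0.076. Without single tumours or pairs, the medians ranged from -0.15 to -0.054 for cAMP-CREB (upward in camera without tumour 6 of the knockdown group or pair 6), from -0.11 to 0.031 for proteases, from -0.044 to 0.032 for pericytes and from -0.12 to 0.74 for skeletal muscle, and Myh1, which did not pass, ranged from -0.0089 to 0.96. Within these ranges camera turned direction, with a preset and an estimated correlation, in several refits. For pericytes these were the refits without knockdown tumour 1 (-0.028), pair 1 (-0.044), control tumour 1 (0.00096) and control tumour 5 (0.0066). For cAMP-CREB they were those without knockdown tumour 6 (-0.080) and pair 6 (-0.054). Proteases turned without knockdown tumour 6 (0.028) and pair 6 (0.016), and skeletal muscle without control tumour 1 (-0.014) and pair 1 (-0.12). Beyond the alternatives' own construction the cause was not tested. Dim genes limit what can be seen: of 19938 genes 11003 were brighter than the median probe set (7.60), and on those alone the hypoxia list missed the threshold.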

Other observations

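The tests of symbol families were chosen after the data were seen. Genes sharing a symbol stem were tested as families of at least 10 bright members. Of 13 Klf genes, which encode zinc finger transcription factors, 7 rose and 1 fell, with a median log2 fold change of 0.22. Of 47 Mrpl genes of the large mitochondrial ribosomal subunit 17 fell and 1 rose (median -0.14), of 15 Nudt hydrolase genes 9 fell and none rose (median -0.22), of 25 Kif kinesin genes 11 fell and 1 rose (median -0.17) and of 10 Anxa annexin genes 6 fell and none rose (median -0.22). These medians kept their sign with quantile normalization. Median centring moves all log2 fold changes by the same small amount, so it could not have changed the sign of these medians. None of 103 families passed camera after Benjamini-Hochberg adjustment (lowest adjusted p = 0.30, and 0.99 with an estimated correlation), although 10 had an unadjusted p under 0.05.

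Many unnamed features changed too: 1617 of the 12146 probe sets with no listed gene and 371 of those with several symbols passed the threshold when all probe sets were tested in limma. Along the gene order, the log2 fold changes of neighbouring genes correlated across genes with a Spearman's rho of 0.329, where the highest of 1000 shuffled orders gave 0.0317, and genes are not independent replicates. Called genes made up 77.4% of the genes inside the 13 runs and 42.8% of those outside. The runs were chosen from the same log2 fold changes, so a higher share inside them follows from that choice. Besides Htr2a to Olfm4, the lower runs with the largest shifts were Ecm1 to Phgdh (34 genes, median -0.49) and Ptdss1 to Pdcd6 (23 genes, -0.43), and the higher ones were Rab23 to Gm10561 (77 genes, 0.27) and Bzw1 to Usp37 (56 genes, 0.27).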
